A study of Mucor circinelloides with 3 samples.

How the data were processed

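The series holds 3 two-colour Agilent arrays, each hybridised with total RNA of 1 light-exposed and 1 dark-grown mycelium of *Mucor circinelloides*. Per the labels, 250000 spores were spread on each 9 cm dish of solid medium at pH 4.5 under a cellophane sheet. RNA was extracted from 50 to 100 mg of ground mycelium with a column kit, and labelled with Agilent's Low Input Quick Amp kit. The series' design text calls the 3 light and 3 dark samples biological replicates.

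Spot and background intensities were deposited as Feature Extraction files, and the authors' scanner software produced them. Per the file headers the version was 10.5.1.1, while the submitters' processing notes name 10.7.3.1. The deposited log10 ratio of red over green equalled that of the processed signals within 0.001 for 97.0%, 96.9% and 97.3% of gene spots on replicates 1, 2 and 3, and was 0 for nearly all others. The authors' deposited value table holds log2 ratios, 1 row for each of 15206 gene spots, and was matched to the spots by position. Its columns had r = 0.983, 0.981 and 0.975 with the scanner's red over green ratios and medians of -0.04, -0.04 and -0.06. Its slopes on the scanner's log10 ratios were 2.99, 2.96 and 3.01, against 3.32 for an exact log2 scale. Its direction was therefore red over green and its scale near log2, though the slopes fell short, and its normalization stays unknown. The files hold median spot signals, so these replaced the mean signals that had been planned.

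Median spot and median local background signals were corrected with limma's normexp method (offset 50) and normalized within each array by loess, with the 536 control spots and the outlier spots at weight 0. Outlier spots made up 0.848%, 0.868% and 0.789% of gene spots and were left out, as were controls. Spots of a gene model were averaged on the log2 scale. Each gene model had 1 probe sequence. A gene model was tested where at least 0.5 of its spots were well above background in one condition's channel on at least 2 arrays. The test was lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all gene models tested at a threshold of 0.05, and a minimum of 2-fold where stated. Before the data were examined, the fit was set to +1 for arrays with light in Cy5 per the labels and -1 for the swapped array, with no dye term. A fit with all 3 arrays read as red over green was added after seeing the data. No fold is given for single gene models that were not well above background in green on any array, since the floor taken from the other gene models lay no higher than their own green signal.

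All 3 arrays lay on 1 slide and were scanned together, so slide and scan give no batch to test. Gene models to name were to be those with an adjusted p under 0.05 and the same direction on all 3 arrays, at most 2 that rose and 2 that fell where IDs have no names. The labelled fit gave 0 such gene models, so the rule was applied to the added fit. Gene lists fixed beforehand by words in the annotation could not be matched, because the files used here pair no ID with a gene name, so no list was tested. No genome was used here, and positions of the gene models are not given.

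The procedure was tested on simulated signals for 9900 gene models, 200 of them changed, run through the same normalization and fit. With array 3 swapped and read as swapped, 56% of gene models changed by 0.5 on the log2 scale, 92% of those changed by 1 and 100% of those changed by 2 or 4 were recovered, with 3 false calls. With no array swapped and read so, the shares were 52%, 92%, 100% and 100%, with 1 false call. With no array swapped but array 3 read as swapped, 0% were recovered at every size. Simulated log2 ratios of 0.5, 1, 2 and 4 were estimated at 0.44, 0.89, 1.82 and 3.39 on average in the first simulation. In the second simulation the averages were 0.45, 0.91, 1.80 and 3.49, so simulated ratios were understated at every size. The changed gene models were drawn at random among those tested, so the amount need not hold for a given gene model. Permutation tests on the arrays used 10000 permutations. They were tested separately on 4000 simulated gene models with fewer permutations. With nothing planted, the test of neighbours, that of classes and that of classes within bins of signal gave p of 0.05 or less in 7%, 7.5% and 7% of 200 draws.

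The alternatives covered background correction, normalization within and between arrays, the filter on dim probes, a dye term, moderation, array weights, the deposited value table, a stricter threshold of 0.01 and leaving out each array.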

Results

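*Mucor circinelloides* is a filamentous fungus of the order Mucorales whose mycelium responds to light. The series asked which genes change their transcript level when dark-grown mycelium is exposed to light. The strain was a leuA mutant that the labels describe as normal in its light responses. Mycelia were grown for 18 days in darkness at 26 °C, and the light-exposed ones then received 20 min of light at 4.8 W per square metre. Total RNA of 3 light-exposed and 3 dark-grown cultures was hybridised as pairs on 3 two-colour Agilent arrays, so that each array compared its own light and dark RNA. The labels place the light RNA in Cy5 (red) on replicates 1 and 2 and in Cy3 (green) on replicate 3.

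Each array carried 15206 spots with gene probes for 10955 gene models, of which 2796 had 2 or more spots. The median red signal was 2250.5 on replicate 1, 1582 on replicate 2 and 3114 on replicate 3, over median local backgrounds of 66, 66 and 96. The median green signal was 917.75, 1077.75 and 744.75, over backgrounds of 29.5, 31 and 30. Between 90.3% and 91.0% of gene spots were well above background in red, and between 90.1% and 91.4% in green. No gene spot was saturated. The pooled SD between repeat spots of a gene model was 0.07 on the log2 scale on each array. Across gene models, the SD of the difference in red over green log2 ratio was 0.18 between replicates 1 and 2, 0.28 between replicates 1 and 3 and 0.27 between replicates 2 and 3. The number of arrays limits the precision of each ratio below.

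The first comparison asked which gene models differed between light and dark when the dyes were taken as labelled. The direction of every ratio in this series is unsettled, because replicate 3 did not behave as a swapped array. Gene models brighter in red on replicates 1 and 2 (labelled light there) were also brighter in red on replicate 3 (labelled dark there). Across 9895 gene models, the red over green log2 ratios of replicates 1 and 2 had a Pearson r of 0.945 and a covariance of 0.26. Replicate 3 had r = 0.857 and a covariance of 0.22 with replicate 1, and r = 0.855 and a covariance of 0.21 with replicate 2. Gene models are not independent replicates, so no p is given for these values. Without dye bias, a swapped array with the same light response would have had negative values. Of 346 gene models at least 2-fold apart in the same direction on replicates 1 and 2, 0 had the opposite sign on replicate 3. The same signs stood in the authors' deposited value table, where r was 0.943, 0.854 and 0.853 for the same pairs of arrays.

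**Figure D1:**
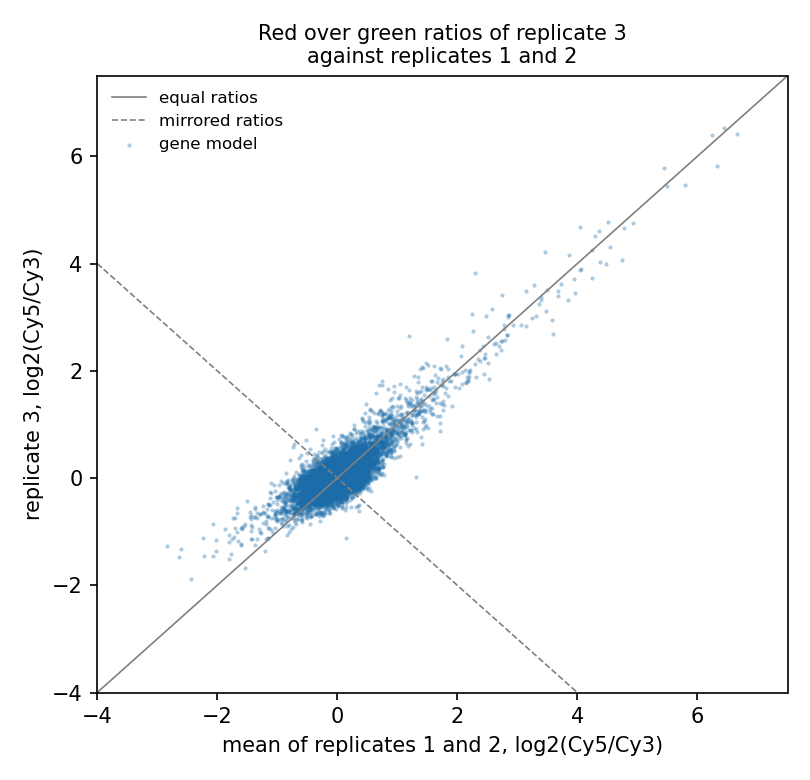
Each point is 1 gene model, with the mean log2(Cy5/Cy3) of replicates 1 and 2 on the horizontal axis and that of replicate 3 on the vertical axis. The solid line marks equal ratios and the dashed line the mirrored ratios of a swapped array with the same response and no dye bias. The points follow the solid line, with r = 0.857 and 0.855 between replicate 3 and each of the other arrays.

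With the dyes as labelled, 0 of 9857 gene models changed between light and dark at an adjusted p under 0.05 in limma's moderated test. At an unadjusted p under 0.05 there were 147, and the smallest adjusted p was 0.915. The largest ratios cancelled in this fit, because replicate 3 entered with its sign turned. Mucci1_96002, for example, had a light over dark log2 ratio of 2.30 with a standard error of 3.13 (adjusted p = 0.915). Leaving out replicate 3 gave 5208 gene models, 2765 higher and 2443 lower in the channel labelled light. Of these, 412 were at least 2-fold apart, with 310 higher and 102 lower. On these 2 arrays light and Cy5 always went together, so a light effect and a dye effect cannot be told apart.

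The second comparison gave the red over green ratio with all 3 arrays read the same way, which turns replicate 3 against its label. It was added after the correlation above was seen. It describes the difference shared by the arrays without settling which channel held the light RNA of replicate 3. If replicate 3 was not swapped, light and Cy5 went together on all 3 arrays. A light effect and a dye effect could then not be told apart in this fit. Of 9900 gene models, 3516 differed between red and green at an adjusted p under 0.05, 1963 higher and 1553 lower in red. At least 2-fold apart were 383 gene models, of which 310 were higher in red and 73 lower. All 310 and all 73 had the same sign on each of the 3 arrays. They were chosen on these same arrays, so this largely follows from the choice. On replicates 1 and 2 red is the channel labelled light, and on replicate 3 it is the channel labelled dark. The fit called 366 of the 412 gene models that replicates 1 and 2 alone called at 2-fold, and all 366 had the same sign. Replicates 1 and 2 are also in this fit, so the overlap is not independent support.

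The differences were uneven in size. The 310 gene models higher in red had a median log2 ratio of 1.48 and reached 6.57, while the 73 lower in red had a median of -1.27 and reached -2.32. At least 4-fold apart were 91 of the former and 4 of the latter, and at least 10-fold apart were 35 and 0. Of the 310, 3 were not well above background in green on any array. They are in the counts and the median, and no fold is given for them. Counted array by array, 236 gene models were at least 2-fold higher in red on each of the 3 arrays and 29 were at least 2-fold lower. At 10-fold these counts were 29 and 0, and at 50-fold they were 4 and 0. No gene model that was at least 1.5-fold higher in red on replicates 1 and 2 was 1.5-fold lower on replicate 3, and the reverse count was also 0.

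**Figure D2:**
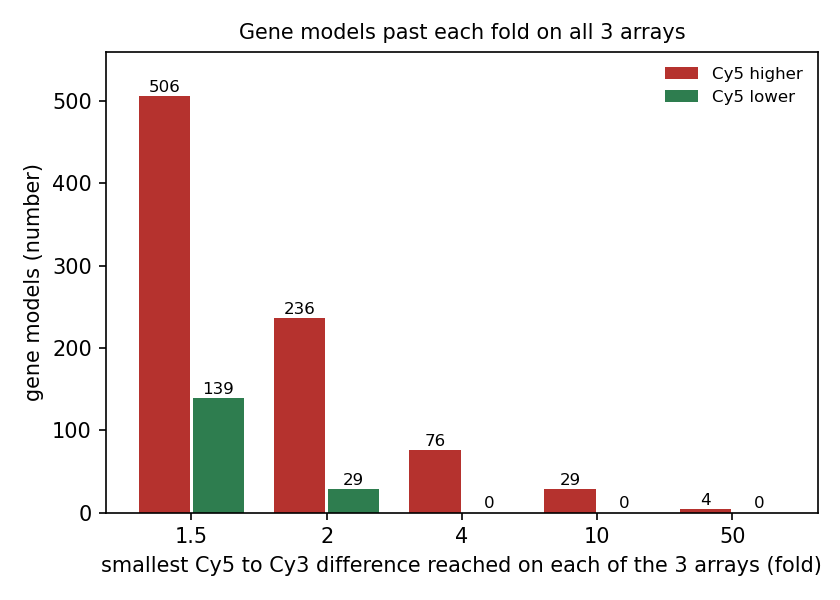
Bars give the number of gene models whose Cy5 to Cy3 difference reached the fold on the horizontal axis on each of the 3 arrays, with Cy5 higher in red and Cy5 lower in green. At 2-fold there were 236 and 29 gene models, and at 10-fold 29 and 0.

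The files give gene model numbers without gene names, so 4 gene models are given as examples, the 2 highest and the 2 lowest in red, with all arrays read the same way. Mucci1_96002 had a red over green log2 ratio of 6.57 ± 0.24 (SD, n = 3), a 95.1-fold difference, with an adjusted p of 6.77e-09. Mucci1_46499 had 6.47 ± 0.05 (SD, n = 3), an 88.4-fold difference, with an adjusted p of 2.80e-09. Mucci1_36772 had -2.32 ± 0.91 (SD, n = 3; adjusted p = 0.000424), which was -2.89 on replicate 1, -2.80 on replicate 2 and -1.27 on replicate 3. Its moderated standard error was 0.27, drawn towards the variance of the other gene models. With the arrays scaled to a common signal, its spread lay in a dim red channel. The mean log2 signal was 7.40 ± 0.89 (SD) in red and 9.72 ± 0.04 in green. Mucci1_96023 had -2.25 ± 0.37 (SD, n = 3), with an adjusted p of 7.77e-06. All 4 were well above background in both channels on the 3 arrays. With the dyes as labelled and no dye term, their adjusted p was 0.915 in each case. A dye term sets replicates 1 and 2 against replicate 3 alone. With it, the light over dark log2 ratio was -0.79 for Mucci1_36772 and -0.28 for Mucci1_96023. It was 0.12 for Mucci1_96002 and -0.043 for Mucci1_46499. The error of replicate 3 is not estimated in that fit, so no p is given for these 4 ratios. Over the 14 alternatives of the labelled fit, the adjusted p ranged up to 0.999976 for each, from 1.60e-13 for Mucci1_36772, 5.53e-12 for Mucci1_96023, 8.11e-17 for Mucci1_96002 and 2.96e-17 for Mucci1_46499, the lowest without replicate 3.

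**Figure D3:**
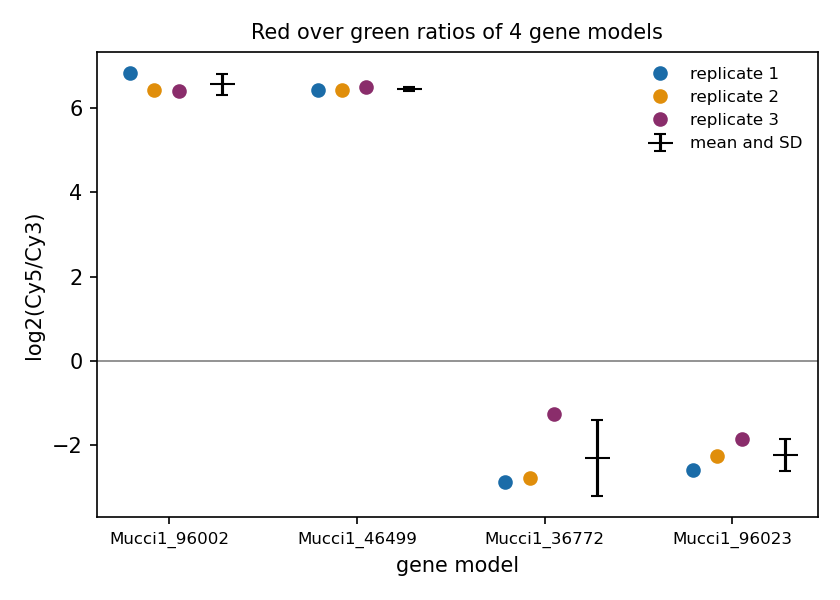
Points give log2(Cy5/Cy3) of 4 gene models on each array, and the black mark beside them the mean with its SD over 3 arrays. Mucci1_96002 and Mucci1_46499 lie near 6.57 and 6.47 on every array, and Mucci1_36772 lies closer to 0 on replicate 3 (-1.27) than on replicates 1 and 2 (-2.89 and -2.80).

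The count of 3516 depended on which arrays entered. It was 1934 without replicate 1, 2272 without replicate 2 and 5229 without replicate 3. The split between higher and lower in red also moved with the scaling. It was 1963 to 1553 in the fit above, 2324 to 1797 with median centring, 1696 to 2029 with Agilent's processed signals and 1564 to 2296 with the authors' deposited value table. At 2-fold the higher side led in each of these, with 310 to 73, 486 to 58, 407 to 133 and 295 to 86.

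A dye effect per gene model can be fitted only if the dyes were swapped as labelled. Under that reading, 4976 gene models had a dye effect at an adjusted p under 0.05, 2715 of them higher and 2261 lower in Cy5, and 371 of them at least 2-fold. They included nearly all of the 3516 gene models called with all arrays read as red over green. The dye effect is a mean of the same red over green ratios, weighted otherwise, so this overlap follows from the design. Under the labelled reading those calls would be dye effects. In the fit with a dye term, the light term compares replicates 1 and 2 with replicate 3 alone, so that one side is a single array. It called 679 gene models, 204 higher and 475 lower in the channel labelled light, and 0 of them were at least 2-fold apart. This fit had 1 residual degree of freedom. Replicate 3 was fitted exactly, so the residual came only from the difference between replicates 1 and 2. The counts of dye effects and of the light term therefore take no account of the error of replicate 3.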

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

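The alternatives of the labelled fit were set before the data were examined, except reading all arrays as red over green. That one, those of the fit with all arrays read as red over green, and those of the dye effect, were added after seeing the data. With the dyes as labelled, the counts of 0 gene models (and 0 at 2-fold) stayed at 0 with other background correction, normalization, filters, moderation, a threshold of 0.01 and the deposited value table. They moved with array weights, to 5835 and 387, where replicate 3 received a weight of 0.11 against 1.54 and 5.87 for replicates 1 and 2. They moved with all arrays read as red over green, to 3516 and 383. The first count moved to 679 with a dye term, while the 2-fold count stayed at 0. Leaving out 1 array gave 0 to 5208, and 0 to 412 at 2-fold, with the upper values without replicate 3. A dye term takes up the red over green ratio shared by the arrays, so the light term sets replicates 1 and 2 against replicate 3. Whether more than this moved the count was not tested. The residual of the fit with a dye term holds no error of replicate 3. The other alternatives that moved these counts turn, leave out or down-weight replicate 3. The ratio of Mucci1_46499 turned from 2.12 to -0.043 with a dye term, and was -0.045 to 6.44 with 1 array left out, below 0 without replicate 1 or 2.

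With all arrays read as red over green, the count of 3516 fell to 1912 at a threshold of 0.01 and ranged from 1934 to 5229 when 1 array was left out, the lowest without replicate 1; the cause of this range was not tested. The count of 383 ranged from 359 to 544 over its 13 alternatives. The dye effect ranged from 4890 to 5343 over 7 alternatives. The 4 named gene models kept their sign and an adjusted p under 0.05 in all 12 alternatives of this fit. Not run were the mean over a gene's probes (each gene model had 1), 1 slide alone (all arrays shared it), the gene list tests (no list could be matched), and a dye effect without 1 array (no residual degree of freedom). The 3 arrays and signals near background limit small ratios.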

Other observations

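The tests of the dyes on replicate 3 and the counts of sign splits were chosen after the results were seen. The tests of gene models with consecutive numbers and of prediction classes were set beforehand.

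Gene models lower in red were closer to 0 on replicate 3 than on the other arrays, while those higher in red differed less. Of gene models at least 2-fold lower in red on replicate 1 (125), the median log2 ratio was -1.16 on replicate 2 and -0.73 on replicate 3, and 96.8% lay farther from 0 on replicate 2. For the 90 chosen on replicate 2, the medians were -1.41 on replicate 1 and -0.85 on replicate 3, and 97.8% lay farther from 0 on replicate 1. Of 328 gene models at least 2-fold higher in red on replicate 1, the medians were 1.39 on replicate 2 and 1.42 on replicate 3, and 52.7% lay farther from 0 on replicate 2. For the 299 chosen on replicate 2, the medians were 1.59 on replicate 1 and 1.52 on replicate 3, and 61.5% lay farther from 0 on replicate 1. The difference between the lower and the higher set was not tested.

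Replicate 3 followed replicates 1 and 2 in red over green. A candidate explanation is that its dyes, or its RNA tubes, were not exchanged as labelled. Among 346 gene models at least 2-fold apart on replicates 1 and 2, the slope of replicate 3 on their mean was 0.858 across gene models, which are not independent, on 1 array. An unswapped array would give a positive slope, and so would a dye bias of each probe. Per the file headers, the spike-in transcripts' ratios had slopes of 0.863, 0.865 and 0.872 on the expected ratios on replicates 1, 2 and 3. Around such a line the scanner's ratios had a residual SD of at most 0.42 on the log2 scale. There are 10 of these transcripts and they do not cover the probes of the gene models, so dye bias and an exchange cannot be told apart. A light response in replicate 3 opposite to that of replicates 1 and 2 stays open and untested.

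For the count of gene models, the signs of 3 arrays allow 4 splits, too few for a share under 0.05. As labelled the count was 0, which any split reaches (4 of 4), and the highest other was 3516. With all arrays read the same way the count was 3516, reached by 1 split, and the highest other was 0. The split with 3516 was chosen after the correlation of the arrays was seen, and restates it.

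Gene models with consecutive numbers were tested for shared ratios, as neighbours under common control might show if numbers followed the genome. Pairs were formed by ID number within a prediction class, and genome positions were not used. Over 2306 pairs, Pearson's r was 0.0454 and Spearman's rho 0.0626, and r lay under 0.0509, the upper end of the central 95% of permutations (two-sided permutation p = 0.0537). The bound set beforehand was not passed, though r lay close to it. Gene models with consecutive numbers need not be neighbours in the genome, so the test cannot decide whether neighbours share ratios. Pairs with both members at least 2-fold higher in red numbered 2, against 2.77 on average over permutations.

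Gene models called at 2-fold with all arrays read the same way were spread unevenly over the prediction classes in their IDs (permutation p = 1e-04, the smallest that 10000 permutations can give). The highest share was 6.39% of 1002 models of the estExt_Genewise class, and the lowest 1.87% of 589 of the gw1 class. In the largest classes it was 5.96% of 2451 models (estExt_fgenesh) and 2.57% of 3773 (fgeneshMC_pg). Their exact 95% intervals were 5.05% to 6.97% and 2.09% to 3.13%. These intervals and the permutation tests of classes treat gene models as independent, although all were measured on the same 3 arrays. Signal level differs between prediction classes too (median log2 signal of 11.48 in estExt_fgenesh and 9.85 in fgeneshMC_pg), and was tested as an explanation. Within 10 bins of signal the permutation p was again 1e-04, and the estExt_fgenesh class held 146 called models against 106.0 expected from signal. The estExt_Genewise class held 64 against 46.7, the e_gw1 class 53 against 56.4 and the fgeneshMC_pg class 97 against 129.2. With bins of this width and gene models taken as independent, a difference in signal level as the whole cause is argued against. The accuracy of the models was not tested.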
